A study of Mus musculus with 8 samples.

How the data were processed

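Total RNA of 8 mouse livers at week 7 was sequenced, 4 libraries per genotype. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with the NEBNext Ultra RNA kit for Illumina. The submitters' processing notes list fastp, STAR, HTSeq, featureCounts, DESeq, DESeq2 and edgeR, without versions or roles, and the mouse build mm10. Which aligner setting, annotation release or strand setting was used is not given in the sources used here.

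The authors deposited 1 table of 27110 genes. It holds whole-number read counts per gene and library, normalised signal values that equal the deposited counts divided by 1 size factor per library, and FPKM values that the authors made from the counts and a gene length. The same deposited table gives the authors' own log2 fold change of LKO over Fl/Fl with its p-value and adjusted p. Each listed gene had at least 2 reads in total. No column of sample values was left unmapped and no row lacked a gene. The reference annotation at hand, GENCODE M21, held 27089 of the gene IDs, and 97.3% of these had the same chromosome, start and end as in the table; coordinates are given as deposited. The authors' deposited fold changes were matched within 0.001 log2 by DESeq2 without a sex term for 99.96% of 16458 genes with a mean of at least 10 reads.

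Groups and sexes were taken from the labels. Replicate numbers differ between the genotypes and pair no samples. The labels give distinct samples but do not state separate litters or preparation days, so p-values measure the spread between these libraries. No 2 libraries held the same values: chi-square per degree of freedom was 35.1 for the closest Fl/Fl libraries, 5 and 7, and no value was near 1.

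Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with genotype as the group (16420 genes), scaled by TMM, and tested with the quasi-likelihood F test (estimateDisp, glmQLFit and glmQLFTest, robust), with terms for genotype and sex over all 8 libraries. Because 1 library is male, the sex term absorbs it, and the genotype effect is that of the 7 female libraries. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. The biological coefficient of variation was 20.4%. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. At 71491723 to 76622375 reads per library, 3 reads in a library are worth 0.0392 to 0.0420 CPM; this floor covers counting error only.

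A total of 42 gene lists of cilium, bile duct, hepatocyte, immune, stromal, stress, clock and sex-biased genes were fixed beforehand. Lists with at least 5 tested genes (41) were tested with camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM under the same design, and the p-values were Benjamini-Hochberg adjusted. Camera with an estimated correlation and fry were run as alternatives.

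The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Pkd1l1; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 1 CPM and all LKO values on one side of the female Fl/Fl values; the 5 higher and 5 lower genes with the smallest p; up to 5 members of each list past the threshold, or its members with the smallest p up to 2 in all; the sex-linked genes; and the most abundant gene of a list where a cell type source is weighed. Predicted genes need not be described. Of the genes picked, 1 is not reported here and was left out of the search for libraries that stand apart. Fos, the respiratory chain genes and the clock genes Dbp and Arntl were named after their values were seen.

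The alternatives set beforehand were a fit without a sex term, the 7 female libraries alone, DESeq2 size factors and upper quartile scaling, no filter beyond 1 read, at least 10 reads in at least 4 libraries, DESeq2 1.42.0, limma voom, limma trend on log2(FPKM + 1), each replicate left out in turn, and stricter thresholds. Other pseudocounts did not apply, since counts were deposited. Alternatives with a term for clock phase, without Fl/Fl 5 and 7, and with trends on gene length or GC content removed were added after seeing the data. The trends were fitted per library by a robust local regression whose settings were not fixed beforehand.

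The procedure was tested on simulated data, with counts drawn from the real means for 16420 genes and 200 of them changed. For this comparison edgeR recovered 81% of changes of 1 on the log2 scale and 97% of changes of 2, and 5.32% of its calls were false. DESeq2 recovered 90% and 100% with 16.3% of calls false. The simulated genes were drawn independently, with no state shared within a library, and only genes above 1 on the log2 CPM scale were changed. The genes called in the data had a median change of 0.72 log2, under the smallest simulated change. These rates therefore need not carry over to the data.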

Results

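Livers with a deletion of Pkd1l1 held more Mt1, Mt2 and Map2k6 RNA and less Junb and Rnd3 RNA than female Fl/Fl livers at week 7. Mt1, a metal-binding protein induced by zinc and stress hormones (chromosome 8, 94179082 to 94180327), rose from 221 ± 11.7 to 577 ± 77.6 CPM (log2 1.38 ± 0.12, adjusted p = 0.00127). Its neighbour Mt2 rose 4.18-fold (log2 2.06 ± 0.24, adjusted p = 0.00954), and Map2k6, a kinase of the p38 pathway, rose 2.68-fold to 14.8 ± 2.28 CPM (adjusted p = 0.00554). Junb, a subunit of the AP-1 transcription factor, fell from 179 ± 19.2 to 48.7 ± 9.66 CPM (log2 -1.88 ± 0.14, adjusted p = 0.00127). Rnd3 fell from 32.6 ± 2.46 to 14.7 ± 2.20 CPM (log2 -1.15 ± 0.12, adjusted p = 0.00554).

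Pkd1l1 encodes a polycystin-family membrane protein. The 4 LKO libraries are of livers with a liver-restricted deletion of it, and the 4 Fl/Fl libraries are their controls. Fl/Fl replicates 5, 7 and 9 and LKO replicates 3, 4, 12 and 13 were labelled female, and Fl/Fl replicate 10 was labelled male. The libraries held 71491723 to 76622375 counted reads. Of 27110 listed genes, 16420 had enough reads to test. The contrast was taken within females (4 LKO against 3 Fl/Fl libraries), with the male library entering under its own sex term. CPM values are mean ± SD, with n = 4 for LKO and n = 3 for female Fl/Fl. Fold changes are log2 of LKO over female Fl/Fl with their standard errors, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

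Pkd1l1 (ENSMUSG00000046634, chromosome 11, 8826708 to 8973266, mm10) was nearly silent in bulk liver in both genotypes. It had 2 reads over the 4 LKO libraries, both in LKO 13, 2 reads over the 3 female Fl/Fl libraries and 0 in the male one. The difference of LKO from female Fl/Fl was -0.00205 CPM (exact permutation test over the 35 splits of the 7 female libraries, two-sided, p = 1). With 3 reads worth 0.0392 to 0.0420 CPM per library, a loss of Pkd1l1 was not detectable at this depth, and the gene could not check the genotype labels. The sex labels could be checked. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 6224, 1264, 1339 and 4153 reads in Fl/Fl 10, and the only reads of them elsewhere were 2 reads of Ddx3y in Fl/Fl 5. Xist, the RNA that silences an X chromosome in females, had 297 reads in Fl/Fl 10 and 49813 to 75650 in the others.

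In all, 232 genes passed an adjusted p of 0.05. Of these, 167 were higher and 65 lower in LKO, 209 were protein-coding, and 67 changed by at least 1 on the log2 scale. In each of the 232, every LKO value lay on one side of every female Fl/Fl value. That held for 15.1% of the tested genes, where splits of 7 libraries into 4 and 3 give 5.71% on average. Genes vary together and the spread of this share over the splits was not computed, so the difference was not tested. The counts rest on single libraries and on the sex term. With genotype alone over all 8 libraries, 1 gene was past the threshold (Mt1, adjusted p = 0.0177), with 654 higher and 663 lower at an unadjusted p under 0.05. The higher and lower counts were 2 and 2 without Fl/Fl 5, 25 and 12 without Fl/Fl 7, 476 and 251 without Fl/Fl 9, 36 and 11 without LKO 4, 111 and 30 without LKO 12, and 44 and 14 without LKO 13. Mt1, Map2k6, Rnd3 and Junb were the 4 genes past the threshold in each of the 8 fits that left out a library.

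**Figure D1:**
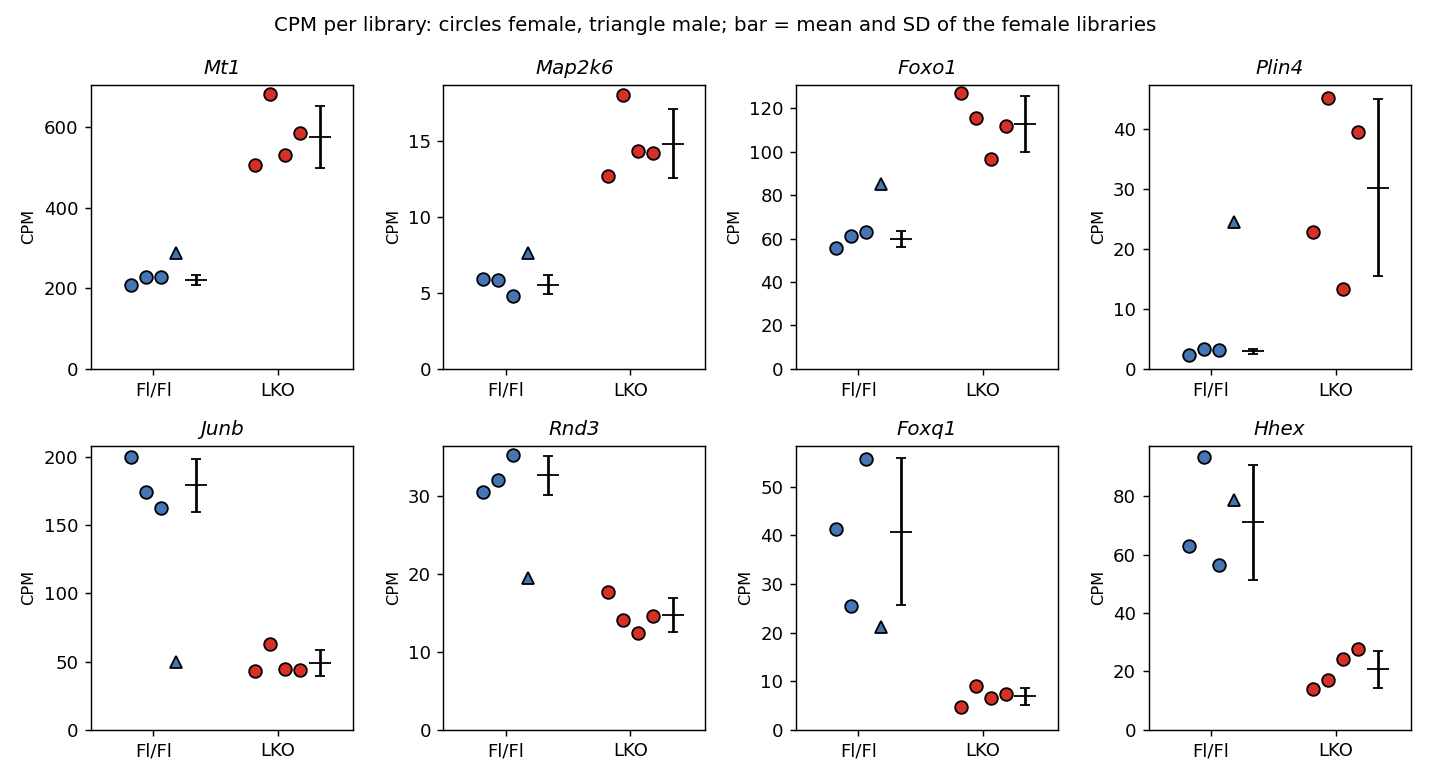
CPM of 8 genes per library, Fl/Fl in blue and LKO in red, with circles for female libraries, a triangle for the male Fl/Fl library, and a bar for the mean and SD of the female libraries of each group. The 4 LKO libraries lie apart from the 3 female Fl/Fl libraries in each panel, while the male Fl/Fl library stands at 289 CPM of Mt1 and 78.7 CPM of Hhex, and at 49.9 CPM of Junb and 24.4 CPM of Plin4. The naming rule required this separation of LKO from female Fl/Fl for all but Foxo1 and Rnd3, which were picked for a small p.

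Plin4, a lipid droplet coat protein, had the largest fitted rise among the genes the naming rule picks. It rose from 2.91 ± 0.48 to 30.2 ± 14.7 CPM (log2 3.37 ± 0.49, adjusted p = 0.0387). The male Fl/Fl library held 24.4 CPM of Plin4, within the LKO range of 13.3 to 45.1. Plin4 lost the threshold in 11 of the 19 other settings described below. Foxo1, picked for its small p, is the insulin-restrained transcription factor of the fasting response and rose 1.89-fold to 113 ± 12.7 CPM (adjusted p = 0.00859). Bcl6, a transcriptional repressor, rose 2.13-fold (adjusted p = 0.0270). Slc10a2, the apical sodium-dependent bile acid transporter that cholangiocytes use to take bile acids back from bile, rose from 21.2 ± 3.69 to 47.9 ± 6.21 CPM (log2 1.18 ± 0.14, adjusted p = 0.00859). The male Fl/Fl library held 71.8 CPM of Slc10a2, above each LKO library (42.2 to 56.7 CPM). Phf11c rose 6.65-fold (log2 2.73 ± 0.33, adjusted p = 0.0204), Ppl, the cornified envelope protein periplakin, 3.21-fold (adjusted p = 0.0422), Treh, the enzyme trehalase, 3.15-fold (adjusted p = 0.0204) and Mdm1, a centriole protein, 2.94-fold (adjusted p = 0.0483). The predicted antisense gene Gm45774 overlaps Mt2, and because the counting is not stated to use strand its rise cannot be told apart from that of Mt2.

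Foxq1, a forkhead transcription factor, fell from 40.8 ± 15.1 to 6.87 ± 1.80 CPM (log2 -2.57 ± 0.31, adjusted p = 0.0195). Hhex, a homeobox factor needed for liver and bile duct development, fell from 71.1 ± 19.6 to 20.7 ± 6.41 CPM (log2 -1.78 ± 0.28, adjusted p = 0.0382). Jun, a partner of Junb in AP-1, fell from 439 ± 171 to 83.3 ± 24.2 CPM (log2 -2.40 ± 0.35, adjusted p = 0.0369). The neutrophil-attracting chemokine Cxcl1 fell by 2.25 on the log2 scale (adjusted p = 0.0322), Phlda1 by 2.01 (adjusted p = 0.0328), Rgs1, a regulator of G-protein signalling, by 1.86 (adjusted p = 0.0300), and Cish, a feedback inhibitor of cytokine receptors, by 1.94 (adjusted p = 0.0130). The predicted genes Gm17024 and Gm15764 were also among the 10 largest falls. Picked for its small p rather than its size, Arhgap29 fell from 103 ± 9.13 to 54.4 ± 5.83 CPM (adjusted p = 0.00859). Dact2 and Tnfaip2, picked in the same way, fell to 5.93 ± 0.44 and 15.0 ± 2.06 CPM (adjusted p = 0.00954 and 0.0127).

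The lists of bile duct and cilium genes in this paragraph held no gene call, and none passed the list test with camera. None of the 28 tested cholangiocyte markers passed the gene test, and the list's median log2 fold change was -0.09 (camera adjusted p = 0.363). The members with the smallest p were Atp1b1, a sodium pump subunit, at 128 ± 14.4 against 87.4 ± 16.7 CPM (adjusted p = 0.0759), and the epithelial cadherin Cdh1 at 62.6 ± 8.24 against 83.9 ± 9.73 CPM (adjusted p = 0.109). None of 32 intraflagellar transport genes passed, and 23 of the fold changes were negative (median log2 -0.04, list adjusted p = 0.122). Its members Ift27 and Ift81 had log2 fold changes of 0.38 ± 0.13 and -0.52 ± 0.19 (adjusted p = 0.189 and 0.215). None of 41 genes of the BBSome and the ciliary transition zone passed, and 30 of the fold changes were negative (median log2 -0.13, list adjusted p = 0.110; 0.0477 with fry in either direction), with Arl3 at log2 0.41 ± 0.12 (adjusted p = 0.126) and Iqcb1 at -0.47 ± 0.15 (adjusted p = 0.146). The 15 tested motile cilium genes and the 7 tested polycystin and fibrocystin genes held no call either (list adjusted p = 0.860 and 0.574). The same was true of 13 hedgehog pathway genes (list adjusted p = 0.168; 1 lower when adjusted over the list alone; 0.0129 with fry in either direction) and 21 planar cell polarity genes (list adjusted p = 0.624). The hedgehog receptor Ptch1 stood at log2 -0.41 ± 0.10 (adjusted p = 0.0919).

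Of 17 Notch pathway genes, 1 passed. Jag1, the Notch ligand whose loss causes paucity of bile ducts, fell from 5.26 ± 1.25 to 2.39 ± 0.31 CPM (log2 -1.13 ± 0.20, adjusted p = 0.0262). The Notch effector Rbpj was at log2 -0.47 ± 0.10 (adjusted p = 0.0547). Adjusted over the list alone, 2 Notch genes were lower, and the list itself did not pass (adjusted p = 0.128). Of 17 targets of the Hippo pathway effector YAP, F3, the coagulation starter tissue factor, fell from 3.71 ± 0.61 to 1.46 ± 0.27 CPM (adjusted p = 0.0175), and Amotl2 had a log2 fold change of -1.22 ± 0.25 (adjusted p = 0.0669). Adjusted over the list alone, 4 of the YAP targets were lower, and the list stood at an adjusted p of 0.0504 with camera, 0.752 with an estimated correlation and 0.0421 with fry.

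With camera's preset correlation, 6 of the 41 tested lists passed. None held with an estimated correlation, and the smallest adjusted p was then 0.752. As a measure of what chance gives, 31 of the 35 ways to split the 7 female libraries into 4 and 3 put at least 6 lists past the threshold, the real one included. The immediate early and heat shock list stood out most. Of its 25 tested genes, Junb and Jun fell and 23 did not pass the gene test, and 23 of the 25 fold changes were negative (median log2 -0.83, camera adjusted p = 1.3e-07, adjusted p = 0.752 with an estimated correlation). When adjusted over the list alone, 8 were lower. With no sex term the median was -0.49 (list adjusted p = 0.00202, the highest over the edgeR fits; the lowest was 2.7e-09). LKO 3 stood between the groups here, at a list median of 0.59 above the mean of the other LKO libraries. Fos, the partner of Jun in AP-1, was chosen after its values were seen: it stood at 298 and 264 CPM in Fl/Fl 5 and 7, at 30.7 in Fl/Fl 9, at 4.78 in the male library and at 4.87 to 12.7 in LKO (log2 -4.63 ± 0.88, adjusted p = 0.0917).

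Of 18 genes of the urea cycle and the periportal zone, 2 rose and 16 did not pass (median log2 0.22, list adjusted p = 0.0117, adjusted p = 0.804 with an estimated correlation). Adjusted over the list alone, 4 were higher. Sds, the serine dehydratase that feeds amino acid carbon into gluconeogenesis, rose from 171 ± 1.58 to 323 ± 42.4 CPM (adjusted p = 0.00881), and the ornithine transporter Slc25a15 rose 1.58-fold to 742 ± 89.8 CPM (adjusted p = 0.0204). Among 32 drug metabolism genes under the receptors CAR and PXR, 2 rose and 30 did not pass (median log2 0.22, list adjusted p = 0.0117, adjusted p = 0.804 with an estimated correlation). The count adjusted over the list alone was 3 higher. These 2 were Nr1i2, which encodes PXR itself (1.65-fold, adjusted p = 0.0134), and Por, the reductase that passes electrons to cytochromes P450 (1.63-fold to 579 ± 87.7 CPM, adjusted p = 0.0306). Both lists lean on single libraries. Without Fl/Fl 9 the urea cycle list had a median of 0.16 (list adjusted p = 0.0853) and the drug metabolism list 0.04 (list adjusted p = 0.902). Over the edgeR fits that kept Fl/Fl 5 or 7 these adjusted p-values were the highest, and the lowest were 0.00134 and 7.7e-06. Without LKO 4 the list medians were 0.13 and 0.12 (list adjusted p = 0.0205 and 0.0268). Without Fl/Fl 5 and 7, which left Fl/Fl 9 as the 1 female Fl/Fl library, they were 0.42 and 0.56. With a trend on gene length removed the drug metabolism list had a median of 0.14 and did not pass (list adjusted p = 0.0577).

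Of 29 acute phase genes, 5 rose and 24 did not pass (median log2 0.19, list adjusted p = 0.0117, adjusted p = 0.804 with an estimated correlation). The counts adjusted over the list alone were 10 higher and 2 lower. With no sex term the list turned to a median of -0.27 (list adjusted p = 0.913, the highest over the edgeR fits, the lowest being 0.00382). Without Fl/Fl 5 and 7, which left Fl/Fl 9 as the only female Fl/Fl library, its median was 0.0033. Without Fl/Fl 7 alone it was 0.13 (list adjusted p = 0.0448), and with a trend on gene length removed 0.11 (list adjusted p = 0.0439). The 5 were Mt1, Mt2, Saa1, Saa3 and Serpina3m. The serum amyloid gene Saa1 rose from 7.62 ± 1.90 to 18.7 ± 3.28 CPM (adjusted p = 0.0204), and the male Fl/Fl library held 932 CPM of it. Saa3 rose to 2.86 ± 0.40 from 1.43 ± 0.33 CPM (adjusted p = 0.0455) and Serpina3m 1.48-fold to 640 ± 77.9 CPM (adjusted p = 0.0387). These families hold close paralogs, so the split of reads among their members is uncertain.

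The male-biased liver list was lower as a set (median log2 -0.31, list adjusted p = 0.0117, adjusted p = 0.804 with an estimated correlation), although 34 of its 35 genes did not pass the gene test and the 1 that did, Bcl6, rose. The list did not pass without Fl/Fl 7 (median -0.25, list adjusted p = 0.115), LKO 3 (-0.25, 0.0522) or LKO 4 (-0.18, 0.0961). Without both Fl/Fl 5 and 7, which left Fl/Fl 9 as the only female Fl/Fl library, its median was -0.11. Without LKO 13 its median was -0.51 (list adjusted p = 0.000248). With no sex term, a fit that counts the male library as a plain Fl/Fl library, the median was -1.58 and the adjusted p the lowest, 6.74e-08. Of 19 B and plasma cell markers, 0 passed alone or adjusted over the list alone, 17 of the fold changes were negative, and the list was lower (median log2 -0.29, list adjusted p = 0.0127, adjusted p = 0.804 with an estimated correlation). That call was lost without LKO 13 (median -0.17, list adjusted p = 0.0761) and with no sex term (-0.08, 0.574, the highest over the edgeR fits; the lowest was 0.00413). Its leading members Cd79b and Ighd were near 1 CPM, at log2 -0.73 ± 0.26 and -0.78 ± 0.29 (adjusted p = 0.197 and 0.217).

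Bile acid and lipid genes held few calls. Of 21 genes of bile acid transport and regulation, Slc10a2 alone passed (list adjusted p = 0.797). None of 17 bile acid synthesis genes did (list adjusted p = 0.751), with Cyp27a1, the enzyme that starts the alternative pathway, at 647 ± 76.3 against 482 ± 47.1 CPM (adjusted p = 0.104). The fatty acid synthesis list (25 tested genes) had a median log2 fold change of 0.12 (list adjusted p = 0.0624). In the cholesterol synthesis list, 1 of 25 fell, Idi1, to 120 ± 6.77 from 179 ± 30.7 CPM (adjusted p = 0.0411; list adjusted p = 0.797). Among 22 pericentral and Wnt target genes, Ahr, the aryl hydrocarbon receptor, rose 1.59-fold (adjusted p = 0.0372). Adjusted over that list alone, 2 genes were higher and 4 lower, so its members went both ways (list adjusted p = 0.751).

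Markers of other liver cells gave few calls. In the extracellular matrix list, 1 of 40 genes passed: Col15a1, a basement membrane collagen, rose 1.54-fold to 18.0 ± 2.63 CPM (adjusted p = 0.0483, list adjusted p = 0.398). Of that list's fold changes, 26 were negative (median log2 -0.11). In the T and NK cell list, 1 of 26 passed, the T cell kinase gene Zap70, which rose 1.66-fold (adjusted p = 0.0270, list adjusted p = 0.686). There, 17 of the fold changes were negative (median log2 -0.13). None of 30 macrophage and Kupffer cell, 22 stellate cell and portal fibroblast or 20 sinusoidal endothelial markers passed (list adjusted p = 0.624, 0.996 and 0.779). Herpud1, an endoplasmic reticulum stress gene, rose to 838 ± 66.5 from 525 ± 66.7 CPM (adjusted p = 0.0204) in a list of 24 with no other call, and Plk2, a p53 target, fell to 8.35 ± 2.03 from 14.9 ± 1.81 CPM (adjusted p = 0.0481) in a list of 17 with no other call. Albumin took 9.88 ± 0.28% of the reads in LKO and 10.7 ± 0.43% in female Fl/Fl, and 5.48% in the male library.

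The male Fl/Fl library, which carries no weight in these fold changes, lay nearer to the LKO mean than to the female Fl/Fl mean in 203 of the 232 genes and nearer to female Fl/Fl in 29. Mt1 (289 CPM), Hhex (78.7 CPM) and Mdm1 (1.37 CPM) were among the 29. In the authors' deposited table, which matches a DESeq2 fit without a sex term, 111 genes had an adjusted p under 0.05, with 70 higher and 41 lower in LKO. Of these, 52 were also called here, in the same direction in each case. The rest of the 232 genes were not called in that table. Mt1 and Hhex, which are among the 29, had adjusted p-values of 2.2e-13 and 1.95e-11 in the authors' deposited table. Slc10a2, Plin4, Jun and Sds did not pass there (adjusted p = 0.849, 0.496, 0.196 and 0.127). In the edgeR fit without a sex term, Hhex had an adjusted p of 0.157.

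**Figure D2:**
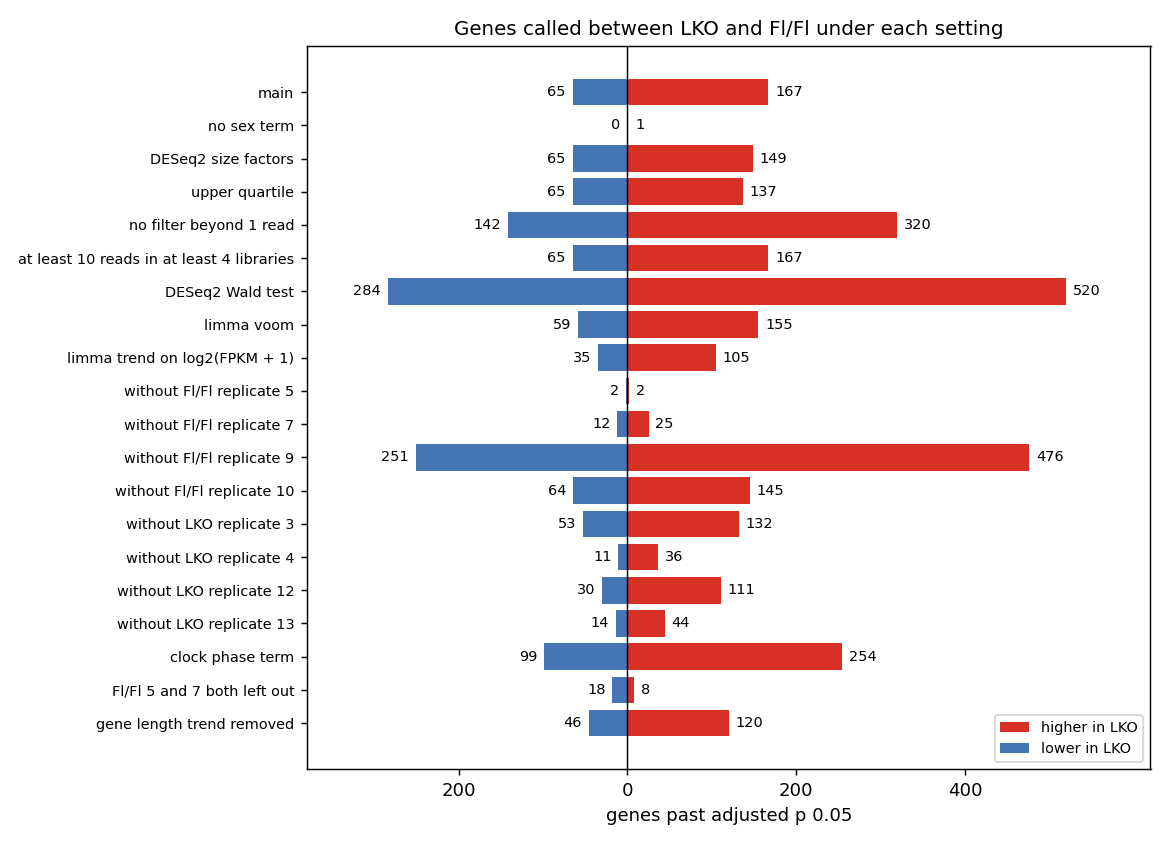
Genes past an adjusted p of 0.05 under each setting, with genes higher in LKO to the right of 0 in red, genes lower in LKO to the left in blue, and the count printed beside each bar. The total ranges from 1 gene without a sex term to 804 genes with the DESeq2 Wald test. The setting with Fl/Fl 5 and 7 both left out sets LKO against 1 female Fl/Fl library.

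**Figure D3:**
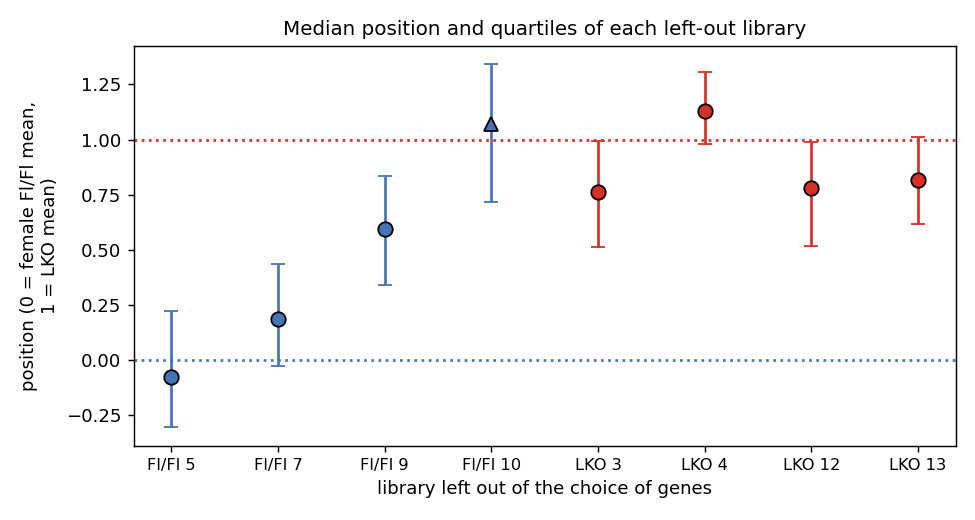
Position of each library along an axis from the female Fl/Fl mean (0) to the LKO mean (1), as the median and quartiles over up to 200 genes. The genes had the smallest p in a fit that left that library out, and the means leave it out too. Each library thus has its own genes and axis, and for Fl/Fl 9 the 0 is the mean of Fl/Fl 5 and 7. The triangle is the male library. Fl/Fl 9 stands at a median of 0.59 and the male library at 1.07, while Fl/Fl 5 and 7 stand at -0.08 and 0.18.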

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

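The tests of positions, clock phase and the male library, and the reading of the other splits, in this part were chosen after the results were seen. A library was singled out when its gap to the nearest of its group of 4, divided by the group's range, passed a limit that 4 values exceed by chance about 1 time in 20. Over 214 such groups, 22 were singled out, and 14 of the 22 were Fl/Fl 10, the male library. A rate of 1 in 20 would give about 10.7. Many of these genes were picked by p-value in a fit where the male library carries no weight, so 10.7 is not a chance level for them.

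Fl/Fl 10 had an Alb share of 5.48% of its reads against 10.4% to 11.2% in the other Fl/Fl libraries. It was high in the acute phase genes Saa1 (932 CPM against 5.42 to 8.76), Saa3 (10.01 against 1.12 to 1.78) and Lcn2 (70.2 against 6.65 to 8.09). Serpina3m of the same list was not high, at 390 CPM against 401 to 456, and the whole list was not tallied for this library. Cyp7b1, a male-biased enzyme, stood at 568 CPM against 32.6 to 54.6. Other high values in Fl/Fl 10 were Plin4 (24.4 CPM), Treh (3.98), B430119L08Rik (27.0), Slc10a2 (71.8), Sds (306.8), Angptl4 (217.8), Col15a1 (23.2), Usp2 (26.5) and mt-Nd4l (31.4). Gm45774 was low in Fl/Fl 5, at 1.32 CPM. Within LKO, LKO 4 was high in Junb (63.2 CPM) and Cd163 (31.8), and LKO 12 in Usp18 (34.5) and mt-Co1 (22090). LKO 13 was low in H2-K1 (1254 CPM), and LKO 3 in Fmo4 (12.7 CPM) and Cela2a (0.316 CPM).

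Among the 35 splits of the 7 female libraries, the real one gave the most called genes. It gave 167 higher genes and the highest of the other 34 splits 7, so 1 of 35 splits was as large. For lower genes it was 1 of 35 again, with 65 against at most 5. This argues against a chance division but cannot exclude one, since 1 of 35 is the smallest share the test can give. The other 34 splits also mix the genotypes, which can lower their counts. For the gene lists the splits gave no argument against chance, since 31 of 35 gave at least 6 lists and the highest of the others gave 17.

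Fl/Fl libraries other than 5 and 7 lay toward LKO at the genes that separate the genotypes. Each library was left out in turn of the choice of up to 200 leading genes and of the female group means. The male Fl/Fl library then lay nearer the LKO mean at 87% of its genes and LKO libraries at 76.5% to 97%. Fl/Fl 5, 7 and 9 did so at 6.60%, 20.7% and 62.8%. A wrong genotype label on the male library may account for its own place, as its 87% is within the LKO range. It cannot account for the place of Fl/Fl 9. In 29 called genes, Mt1 and Hhex among them, the male library lay nearer female Fl/Fl. LKO libraries left out in turn also lay nearer female Fl/Fl at some genes, so that count does not speak against a wrong label. A state of Fl/Fl 5 and 7 that the other libraries lack stays open too: Fl/Fl 9 had a median position of 0.59 (quartiles 0.34 and 0.84), between the groups. A difference between the sexes, with the male at a median of 1.07, cannot be told apart from these with 1 male library, and an effect of genotype in females remains open beside them.

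Immediate early genes were low in LKO relative to each of the 3 female Fl/Fl libraries: over the 25 listed genes, Fl/Fl 5, 7 and 9 stood at medians of 0.86, 1.03 and 0.94 log2 above the LKO mean. LKO 3 stood at 0.59 above the mean of the other LKO libraries, so the group does not divide cleanly. The libraries also split by clock genes, with Dbp at 0.606 to 3.50 CPM in Fl/Fl 5 and 7 and LKO 3 and 4, and at 26.9 to 54.4 CPM in the rest. This split follows the replicate numbers in both genotypes, the lower numbers having the low Dbp, and the labels give no reason. Within Fl/Fl it is the same division as that of 5 and 7 from 9 and 10. With a term for clock phase the list's median was -0.86 (quartiles -1.66 and -0.26) against -0.83 without it. Both genotypes are in both phases, so the term could move the median little. Over the list, Fl/Fl 9, of the phase with high Dbp, stood as high as Fl/Fl 5 and 7. This argues against a difference between the phases as the cause of the list's median only. Fl/Fl 9 is the 1 female Fl/Fl library of its phase. Fos (30.7 against 298 and 264 CPM) and Jun (251 against 583 and 484 CPM) were lower in it than in Fl/Fl 5 and 7. Time of day within a phase stays open, since the term cannot see it. A response to handling before collection may have raised these genes in the female Fl/Fl animals. The male Fl/Fl library stood at a median of -0.48 relative to LKO, but with 1 male library and no handling record in the labels this cannot be told apart from sex or from the genotype itself.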

How the results depend on the processing

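The clock phase, length trend and joint removal settings were chosen after seeing the data. No paired analysis was possible because the 2 genotypes share no replicate numbers. Genes higher and lower in LKO numbered 167 and 65. They numbered 1 and 0 with no sex term (edgeR; 654 and 663 at an unadjusted p under 0.05), 320 and 142 with no filter, 520 and 284 with DESeq2, and 105 and 35 with limma on FPKM. An adjusted p under 0.01 left 14 and 4, and a log2 change of at least 1 left 36 and 31. With a clock phase term they were 254 and 99 (225 of the genes shared with the 232), and without Fl/Fl 5 and 7 they were 8 and 18 (8 shared). Leaving out 1 replicate gave 2 to 476 higher and 2 to 251 lower genes, the lowest without Fl/Fl 5 and the highest without Fl/Fl 9. Fewer libraries can lower a count by construction, while the rise without Fl/Fl 9 goes the other way; the cause was not tested. Other scalings, voom, the females alone, the filter at 10 reads and the length trend kept both counts within 1.5 times, and the median log2 of all genes was -0.0032, or -0.0072 and -0.0179 with the other scalings.

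The 6 lists became 13 with no sex term, 10 with no filter, 0 with an estimated correlation, and 7 to 12 with 1 replicate left out. Fry gave 2 (the immediate early and the YAP target lists), or 16 in either direction. The Pkd1l1 difference was 0.000108 CPM with no sex term and ran from -0.00864 to 0.000153 CPM with 1 replicate left out, all within a few reads; voom gave no Pkd1l1 value because the gene was filtered, and DESeq2 gave log2 -0.38. Of 43 genes past the threshold that the naming rule picks, 41 kept their sign in each of the 19 other settings. In each called gene the LKO values lay on one side of the female Fl/Fl values. Leaving out a library or rescaling could therefore hardly turn a sign, and this count is no measure of stability. Saa1 and Saa3 turned to -3.67 and -0.32 with no sex term, a fit that counts the male library, where both stand high, as a plain Fl/Fl library. Mt1 stayed past the threshold in each of the 19 settings. Map2k6, Rnd3 and Junb lost it in 1 setting, the fit with no sex term (adjusted p = 0.0576, 0.200 and 0.451). Of the 43 genes, 39 lost it without Fl/Fl 5. Mdm1 and Col15a1 each lost it in 14 settings, Saa3 in 12, Plin4 in 11 and Ppl in 10. Depth limits Pkd1l1, which had at most 2 reads in a library.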

Other observations

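The tests of the respiratory chain genes, gene length, GC content and clock phase in this part were chosen after the values were seen, while the fixed lists were set beforehand. Nuclear-encoded subunits of the respiratory chain and ATP synthase, a group outside the fixed lists, were mostly higher in LKO. Of 77 tested, 14 passed the gene test as higher and 0 as lower, and 67 had a positive fold change (median log2 0.24, quartiles 0.08 and 0.40). Cox5b rose by log2 1.06 ± 0.13 (adjusted p = 0.00881), Uqcr11 by 1.05 ± 0.13 (adjusted p = 0.00954), Ndufs6 by 0.90 ± 0.13 (adjusted p = 0.0134) and Cox8a by 0.77 ± 0.12 (adjusted p = 0.0175). With no sex term, 0 of the 77 passed and the median was 0.12. The 13 mitochondrially encoded genes had a median of -0.13 (list adjusted p = 0.122), with mt-Co1 at 20092 ± 1350 CPM in LKO and 24609 ± 3433 in female Fl/Fl (adjusted p = 0.270). Mitochondrial RNA took 5.04 ± 0.26% of reads in LKO and 5.97 ± 0.51% in female Fl/Fl.

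These subunit genes are short, and short genes were higher in LKO in general. Over protein-coding genes in 10 classes of length, the median log2 fold change fell from 0.13 in the shortest class to -0.10 in the longest, and 45 higher and 1 lower calls were in the shortest. A trend on gene length between libraries could account for part of the rise: with it removed per library, the median of the 77 was 0.12 (quartiles 0.01 and 0.28) and 10 still passed. With trends on length and GC content removed the median was 0.11 and 6 passed. Among 10000 random lists matched on length and expression, 0 had as high a median as the subunits, although genes that vary together make such lists too narrow a yardstick, and camera with an estimated correlation gave the group an unadjusted p of 0.115. About as much of the shift went with the trend as remained. The limit for excluding a length effect was itself changed after the first result was seen: it was first that the median keep over 0.5 of its value with a lower quartile above 0, which 0.1235 of 0.2406 met by a narrow margin, and it was then raised to 0.75 of its value, which it misses. The smoother was also chosen without a plan, and fits with other smoothers are not given here. An effect on these genes and a length effect therefore cannot be told apart.

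Other fixed lists held at most 1 call each. The circadian clock list (20 genes) had a median log2 of 0.24 (adjusted p = 0.308), with Ciart at 1.63 ± 0.44 (adjusted p = 0.148) and Usp2 at 1.87 ± 0.51 (adjusted p = 0.155). With terms for genotype and sex, 44 genes differed between the 4 libraries with Dbp above Arntl and the 4 with it below, and 0 of them were among the 232. Sets of 44 and 232 among 16420 genes would share few genes by chance, so this 0 says little about the clock's part in the calls. The interferon response list (36 genes) had a median of 0.12 (adjusted p = 0.1204), with 3 genes higher when adjusted over the list alone, and Usp18 stood at log2 0.87 ± 0.19 (adjusted p = 0.0683). The gluconeogenesis list had 3 of 13 genes higher when adjusted over the list alone (list adjusted p = 0.122), with Ppargc1a at 38.8 ± 14.7 against 18.2 ± 1.62 CPM (adjusted p = 0.114). Hepatocyte markers had 2 of 25 higher on that count (list adjusted p = 0.308), with Hnf4a at log2 0.47 ± 0.11 (adjusted p = 0.0646). Fatty acid oxidation, female-biased liver, cell cycle and oxidative stress lists had adjusted p-values of 0.122, 0.0762, 0.437 and 0.329. Those of neutrophil, antigen presentation and erythroid genes had 0.860, 0.122 and 0.730. The chemokine and cytokine list, in which Cxcl1 was the 1 call among 27 tested genes, had 0.363, and the adipose and muscle list, in which Plin4 was the 1 call among 5 tested genes, had 0.489. The endoplasmic reticulum stress list, with Herpud1 as its call, had 0.751, and the p53 list, with Plk2, 0.815. The pancreas and gallbladder list had 3 tested genes, too few for the list test, and 0 calls.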
